A study of Rattus norvegicus with 9 samples.

How the data were processed

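RNA from the thalamus of young male Wistar rats was measured on 9 single-colour oligonucleotide arrays, 4 from rats kept on ordinary pelleted chow and 5 from rats fed the diet as a powder. Per the labels, total RNA was extracted with TRIzol and purified on RNeasy columns, and biotin-labelled cRNA was prepared from 100 ng of it. Groups and replicate numbers were taken from the sample titles. The labels speak of 10 rats and 9 samples were analysed here. They do not state separately for each sample which animal it came from, so the p-values measure the spread between these samples, part of which could be technical.

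The deposited table gives 1 log2 expression value per probe set and array for 31099 probe sets. The software, background correction, summarisation and normalization used by the authors are not given in the sources used here. That the values are on a log2 scale was read from their range, 5.37 to 14.0, and any centring applied before deposit stays unknown. The array medians were 7.39 to 7.40 on the chow arrays and 7.40 on each powder array, so no further normalization was applied. All columns of the table were used. Scanner files and detection calls were not analysed here, so no background level or detection limit could be set. With 4 and 5 arrays per group, the number of arrays limits the precision of each value.

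The values were strongly compressed before deposit for most probe sets. For 26193 of the 31042 rat probe sets (84.4%), the 9 values spanned less than 0.01 log2 units, with a median span of 0.000475, and for the other 4849 the median span was 0.424. Differences on the compressed probe sets carry a test result but almost no size. For this reason, counts are given both for all probe sets and for those spanning at least 0.01. That limit was chosen after the data had been examined.

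Probe sets were named through the platform annotation, in which 20826 had 1 gene symbol, 436 had several and 9780 had none listed. No gene was named from a probe set with several symbols. Of the 14217 genes, 14204 had a symbol in the RefSeq gene table of assembly GRCr8, and 0 symbols were updated. A gene was represented by its single-symbol probe set of highest mean value. No genome build is named for the array, so no coordinates are given.

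Chow was compared with powder in R 4.3.3 with limma 3.58.1, using lmFit and eBayes on the log2 values as deposited, after 57 control probe sets had been left out. Differences are chow minus powder. Features with a Benjamini-Hochberg adjusted p under 0.05 were called. The test was run once over all rat probe sets and once over the genes. Values are given as the log2 difference ± SE from limma unless group means ± SD are stated, and folds are 2 raised to that difference.

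The test, its covariates (none), the naming rule and 36 gene lists were fixed before the data were examined. The lists covered GABA, glutamate, monoamine and neuropeptide signalling, spines and the postsynaptic density, synaptic vesicles, ion channels, immediate early, clock, glucocorticoid, heat shock, ribosomal protein, oxidative phosphorylation, axon guidance and cholesterol genes, and markers of thalamic neurons, neighbouring regions, glia, vessels, blood and dividing cells. Each list was tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists. Its members were also counted with p adjusted over the list alone. A list score was the mean over members of each value minus that gene's mean over the 9 arrays, and scores were compared by two-sided exact permutation tests, whose smallest possible p was 0.00794.

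The naming rule took, in each direction, the 12 genes with the largest absolute difference among called genes whose groups did not overlap. It added the 4 members of smallest p from the GABA receptor, GABA synthesis and spine lists and from every list past the camera threshold. It also added genes fixed in advance, among them Gad1, Gad2, Slc32a1, Dlg4 and Bdnf, in any case, and up to 4 members per list with p under 0.05 adjusted over the list alone. Other list members in the text were named after their values had been seen, chiefly because their probe sets were not compressed.

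The alternatives chosen before the data were examined were a trended robust variance, quantile normalization, subtraction of array medians, leaving out the dimmest probe sets, array weights, the replicate number as a block, leaving out each array in turn, the median over a gene's probe sets, an equal-variance test without moderation, a rank product, an adjusted p under 0.1, and for the lists an estimated correlation, camera on ranks and fry. Those added later were leaving out the compressed probe sets, a covariate from the 5' and 3' probe sets of the beta-actin control, and a minimum difference of 0.1. The label numbers were also checked for pairing between the groups.

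The fitting steps were tested on simulated data for chow against powder with the 14217 genes, 4 and 5 arrays and the genes' own spread. Of 67 genes shifted by 2 standard deviations, 5 were recovered (7.46%), of 67 shifted by 4, 45 were recovered (67.2%), and of 66 shifted by 8, 66 were recovered (100%). In that simulation 7 unchanged genes were called, and 0 genes were called where nothing had been changed. Both of the 2 shifted lists and 0 other lists passed the camera threshold. Genes were drawn independently of each other there, so the simulation does not measure false calls of genes or lists where genes are correlated.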

Results

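The data were genome-wide expression profiles of the thalamus, the relay station between the sense organs, brainstem and cortex, from weanling male rats. The rats were 3 weeks old at the start and kept under a 12-12 h light-dark cycle. The labels also give an age of 5 weeks for each sample. After 2 preparatory days on powder, groups balanced by weight received chow or powder for 8 days. Pelleted chow has to be chewed and powder does not, and the comparison addressed whether chewing after weaning changes thalamic gene expression, with GABAergic transmission and dendritic spines as the stated interest. There were 4 chow and 5 powder arrays, each with 31042 rat probe sets standing for 14217 named genes. Correlations between the arrays over all rat probe sets ranged from 0.991 to 0.999.

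Among called genes, the largest differences were 0.53 and -0.60. Higher under chow were Ralgps2, an activator of Ral GTPases (1.44-fold, log2 difference 0.53 ± 0.054, adjusted p = 0.0021), Cpne3, a calcium-dependent membrane-binding protein (0.52 ± 0.057, adjusted p = 0.00227), and Kif1a, the kinesin that carries synaptic vesicle precursors along axons (0.50 ± 0.075, adjusted p = 0.00474). Lower under chow were Tbl1x, a subunit of a nuclear co-repressor complex (0.66-fold, -0.60 ± 0.056, adjusted p = 0.00178), Col11a2, a collagen chain (-0.57 ± 0.061, adjusted p = 0.00217), and Bicral, a subunit of a chromatin remodelling complex (-0.51 ± 0.038, adjusted p = 0.00143). By the naming rule, all 4 chow arrays lay on one side of all 5 powder arrays for each of these genes. Kif1a was at 10.4 ± 0.119 under chow and 9.89 ± 0.113 under powder (mean ± SD, n = 4 and 5), and Tbl1x was at 8.49 ± 0.125 and 9.09 ± 0.034.

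The genes that follow are likewise limited to called genes whose groups did not overlap. Gad2, at 0.60, was not called and so is not among them. The other genes of largest increase under chow were Csrnp3 (0.52), the ubiquitin ligase Herc1 (0.50), Tac1, the precursor of substance P (0.49), the vesicle-traffic GTPase Rab14 (0.47), the kinase Gsk3b (0.47), Plcxd3 (0.45), Pnma8b (0.45), the netrin receptor Unc5b (0.44) and the co-chaperone Dnajb14 (0.43), with adjusted p from 0.0014 to 0.0352. The other genes of largest decrease were Leng8 (-0.51), the kinesin Kif1c (-0.50), Ermard (-0.49), the long noncoding RNA Miat (-0.49), the neuronal transmembrane collagen Col25a1 (-0.48), Catsperz, a subunit of the sperm calcium channel (-0.48), the kinase Stk35 (-0.47), the RNA-binding protein Tia1 (-0.47) and the phosphatase inhibitor Ppp1r17 (-0.46), with adjusted p from 0.00162 to 0.0329. A second uncompressed probe set went the same way for Kif1a (0.64), Herc1 (0.40), Unc5b (0.31), Dnajb14 (0.33) and Pnma8b (0.19), all called. Rab14 had 4 uncompressed probe sets, at 0.47, -0.37, 0.18 and -0.20. Compressed probe sets were called the other way for Kif1a (-0.00028), Tia1 (0.000296), Stk35 (0.000346) and Bicral (0.000157). Taking the median over a gene's probe sets, Tbl1x had a difference of 0.00025 (adjusted p = 0.185). Tac1 was no longer called without any 1 of 6 arrays, chow 2 and each powder array (adjusted p from 0.0542 to 0.0713). Ppp1r17 was likewise not called without chow 3 or any 1 powder array (0.0543 to 0.0693), and Plcxd3 without chow 4, powder 1 or powder 2 (0.0506 to 0.0526).

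**Figure D1:**
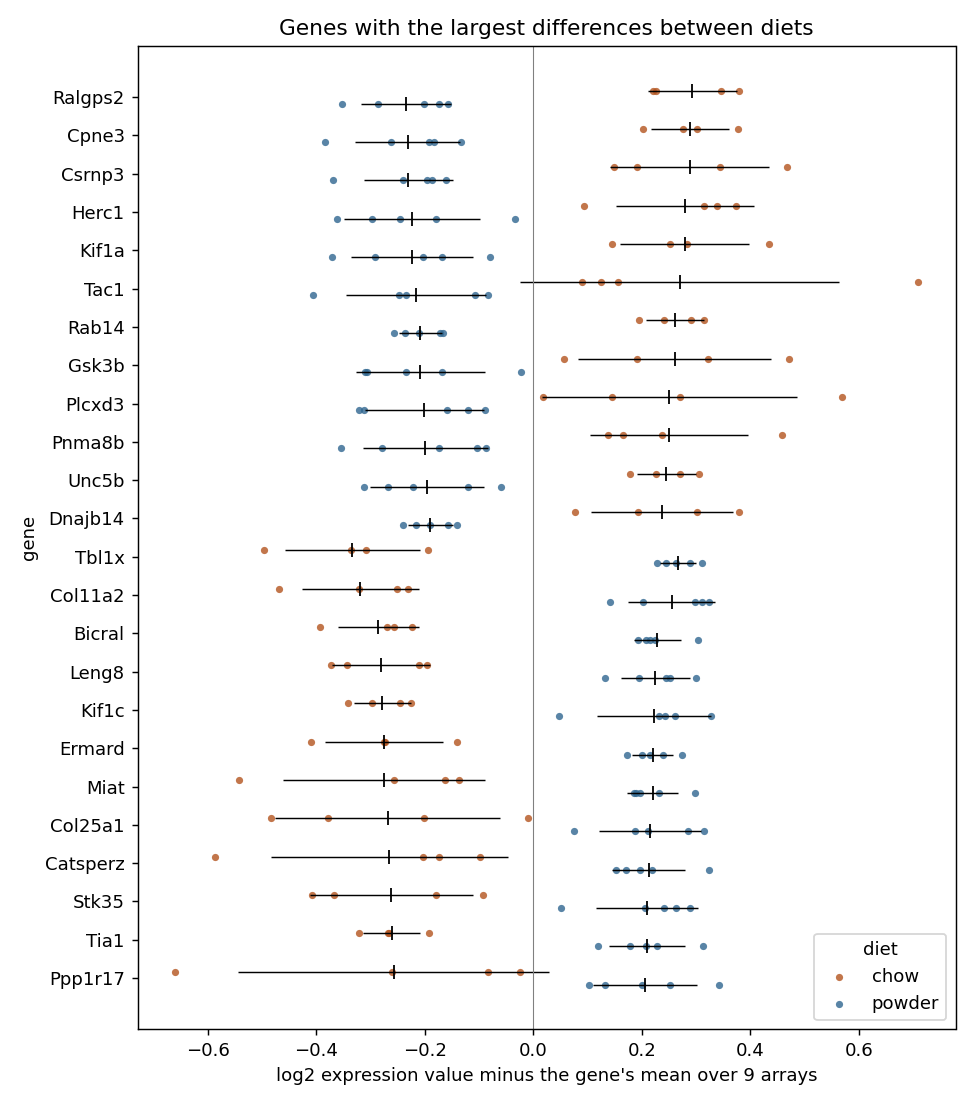
Log2 expression of the 12 genes with the largest differences in each direction among called genes whose diets did not overlap. Each gene's mean over the 9 arrays is subtracted. Points are arrays (4 chow, 5 powder) and bars are group means ± SD. The lack of overlap was part of the choice, and the genes run from Ralgps2 (0.53 higher under chow) to Tbl1x (-0.60).

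Over all genes, 4684 of 14217 (32.9%) differed between the diets, 2015 higher and 2669 lower under chow, and over all probe sets 10753 of 31042 (34.6%), 5558 higher and 5195 lower. Among the 2414 genes spanning at least 0.01 log2 units, 1189 (49.3%) were called, 218 higher and 971 lower under chow, with a median absolute difference of 0.221. Differences among called genes were small, since 0 of them differed by more than 1 log2 unit and the extremes were 0.53 and -0.60. The groups did not overlap for 1589 of the higher and 2279 of the lower genes, where chance gives 1.59% of genes. Array medians differed slightly (7.3936 ± 0.0024 under chow and 7.4001 ± 0.0017 under powder, SD, exact permutation p = 0.00794, adjusted p = 0.0159). Both scaling alternatives moved 94% or more of the called compressed genes by more than their 9 values span (median moves 0.00869 and 0.00657, median span 0.000465), so their directions after rescaling were set by the rescaling. The split of all probe sets was 15610 higher and 1854 lower after quantile normalization, and 27206 higher and 2141 lower after subtraction of array medians. Among the genes spanning at least 0.01 the split remained toward lower calls, at 348 and 988 with quantile normalization and 327 and 1133 with medians subtracted. By list, higher calls outnumbered lower ones in 20 of 36 lists on the values as deposited and in 35 under each scaling alternative. The probe sets higher under chow numbered 3661 without powder 1. Without chow 1, 3569 genes were called, 1368 higher and 2201 lower.

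GABA signalling genes, the first stated interest, showed few calls on the values as deposited. Of 18 GABA receptor subunits, 3 were higher under chow and 0 lower (2 and 0 adjusted over the list alone). Gabra3, the alpha3 subunit prominent in the thalamic reticular nucleus, rose 1.17-fold (0.23 ± 0.066, adjusted p = 0.0338), and Gabrr3 and Gabra6 passed the test on compressed probe sets with differences of 0.00046 and 0.00066. Gabrg1 had a difference of 0.24 ± 0.085 (adjusted p = 0.0656) and was not called. Without chow 1 its difference was 0.153. Of 22 genes of GABA synthesis, transport and synapse, Gabarap, which binds GABA-A receptors, rose by 0.11 ± 0.031 (adjusted p = 0.0302) and Nlgn2, the neuroligin of inhibitory synapses, was lower by a compressed -0.00023; adjusted over the list alone the counts were 0 higher and 1 lower. Gad2, an enzyme of GABA synthesis, had the largest difference, 0.60 ± 0.199 (8.48 ± 0.416 under chow and 7.88 ± 0.183 under powder, SD, n = 4 and 5), with adjusted p = 0.0536. The companion enzyme Gad1 differed by 0.075 ± 0.137 (adjusted p = 0.689) and the vesicular transporter Slc32a1 by 0.25 ± 0.186 (adjusted p = 0.312). Without chow 1, Gad1 was at -0.0635 and Slc32a1 at 0.103, neither called. A second uncompressed Gad1 probe set, of lower mean value, was at 0.45 ± 0.196 over all arrays (adjusted p = 0.108, not called).

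Counts for both GABA lists depended on scaling: receptors gave 5 higher and 1 lower after quantile normalization and 11 and 1 with medians subtracted, and synthesis, transport and synapse genes gave 11 and 0 and 15 and 0. Neither list passed camera, which compares a list with all other genes (adjusted p = 0.137 for receptors, whose position relative to other genes turned to lower under both scaling alternatives, and 0.607 for synthesis, transport and synapse). Calls on these genes depended on single arrays: Gabra3 was lost without any 1 of 6 arrays (chow 1 and 3, powder 1, 2, 3 and 5, with adjusted p from 0.0529 to 0.0816) and Gabarap without powder 1, 2 or 4 (0.0583 to 0.0658). Gad2 was called without chow 1 (0.39, adjusted p = 0.0413).

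Of 28 uncompressed spine and postsynaptic density genes, the second stated interest, 10 were lower under chow and 0 higher, against 971 lower and 218 higher of all 2414 such genes. Dlg3, a scaffold that anchors glutamate receptors, fell by 0.34 on the log2 scale (-0.34 ± 0.030, adjusted p = 0.00177), the scaffold Shank1 was at -0.33 ± 0.072 (adjusted p = 0.0145), and Trio, an activator of Rac in spines, was at -0.31 ± 0.054 (adjusted p = 0.00731). Wasf1, which drives actin branching in spines, was at -0.21 ± 0.030 (adjusted p = 0.00424). Also lower were the transcription factors Mef2a (-0.29) and Mef2c (-0.27), Fmr1 (-0.25), the Rac activator Tiam1 (-0.22), the kinase subunit Camk2b (-0.13) and Srgap2 (-0.012), the last of which reversed to 0.0081 after quantile normalization. Of 65 measured members, 14 were lower and 4 higher under chow (12 and 3 adjusted over the list alone), and all 4 higher ones, among them Wasf3, were on compressed probe sets.

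That split turned to 11 lower and 37 higher after quantile normalization and to 14 lower and 39 higher with medians subtracted. The list did not pass camera (adjusted p = 0.137), and fry, which asks only whether its members move one way on balance, gave adjusted p = 0.00232 toward lower. Its score was lower on all 4 chow arrays than on all 5 powder arrays (-0.029 ± 0.0071 and 0.023 ± 0.0079, SD, exact permutation p = 0.00794, adjusted p = 0.0476). A second uncompressed Dlg3 probe set was called in the other direction (0.24, adjusted p = 0.0195), and by the median over its probe sets Dlg3 was at 0.0046 and not called. A second probe set of Mef2c was at 0.093 (not called). Dlg4, the gene of PSD-95, had its highest probe set compressed and not called, and another at -0.18 (adjusted p = 0.0302), while Bdnf was compressed and not called.

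Glutamate receptor genes went both ways. Of 26 ionotropic subunits and auxiliary proteins, 7 were higher and 3 lower under chow (7 and 3 adjusted over the list alone; camera adjusted p = 0.404). Higher were Cacng4, an AMPA receptor auxiliary subunit (0.39 ± 0.056, adjusted p = 0.00429), the NMDA receptor subunits Grin3a (0.27) and Grin2a (0.23) and the kainate receptor partner Neto2 (0.13), and lower were the kainate subunit Grik2 (-0.30) and Cacng2, the gene of stargazin (-0.25). Of 13 metabotropic receptor and transport genes, 1 was higher and 0 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.944). Among 44 synaptic vesicle genes, 2 were higher and 3 lower (0 and 1 alone; 0.944), with the calcium sensor Syt1 at 0.42 and synaptophysin, Syp, at -0.17. Among 17 calcium and HCN channel genes, 2 were higher and 2 lower (1 and 1 alone; 0.965), including Cacnb4 (0.25) and Cacna1b, the N-type channel (-0.13). Among 49 potassium channel genes, 5 were higher and 5 lower (4 and 2 alone, camera adjusted p = 0.801). Of the 18 uncompressed ones, 3 were called, all lower, against 971 lower and 218 higher of all 2414 such genes. They were Kcnab2 (-0.24), Kcnc1 (-0.18) and Kcnj11 (-0.12). Among 12 sodium channel genes, 0 were higher and 2 lower (0 and 2 alone; 0.846), with 1 called probe set of Scn2b at -0.39 and another at 0.23. With 1 array left out in turn, ionotropic calls ranged from 4 to 7 higher and 0 to 4 lower, potassium channel calls from 3 to 6 higher and 2 to 10 lower (10 without chow 3), calcium and HCN channel calls from 1 to 3 higher and 1 to 4 lower, and synaptic vesicle calls from 0 to 2 higher and 1 to 2 lower. After quantile normalization and with medians subtracted, higher and lower calls were 16 and 2 and 20 and 3 for ionotropic genes, 5 and 0 and 6 and 1 for metabotropic genes and 23 and 1 and 32 and 3 for vesicle genes. They were 11 and 2 and 12 and 2 for calcium, 21 and 5 and 31 and 9 for potassium and 6 and 1 and 5 and 1 for sodium channels.

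Ribosomal protein genes and genes of mitochondrial oxidative phosphorylation were higher under chow as groups. After quantile normalization 8329 of all 14217 genes were higher and 1000 lower. In these lists, 21 ribosomal protein genes were then higher and 0 lower, and 39 oxidative phosphorylation genes were higher and 1 lower. Their position relative to other genes in camera turned to lower there (adjusted p = 0.295 and 0.397). Of 42 measured ribosomal protein genes, 17 rose and 0 fell (23 and 0 adjusted over the list alone; camera adjusted p = 1.85e-07, and adjusted p = 0.652 with an estimated correlation), with Rps15a at 0.21 ± 0.033, Rpl23 at 0.17 ± 0.024 and Rpl34 at 0.12 ± 0.016. Of 67 respiratory chain and ATP synthase genes, 23 rose and 0 fell (27 and 0 adjusted over the list alone; camera adjusted p = 2.02e-07, and adjusted p = 0.652 with an estimated correlation), with the ATP synthase subunit Atp5pb at 0.17 ± 0.027 and the complex I subunit Ndufb10 at 0.14 ± 0.020. With medians subtracted the adjusted p was 0.316 and 0.0984. The 17 ribosomal protein calls became 11 without powder 1, powder 2 or powder 5. The ribosomal protein score was higher on all 4 chow than on all 5 powder arrays (0.038 ± 0.034 and -0.031 ± 0.014, SD), as was the oxidative phosphorylation score (0.012 ± 0.0089 and -0.0096 ± 0.0084), each with exact permutation p = 0.00794 and adjusted p = 0.0476. With chow 1 left out the score differences were 0.053 and 0.022.

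Monoamine, acetylcholine and histamine signalling genes, neuropeptide genes and pineal markers also passed camera toward higher under chow (adjusted p = 0.000837, 0.0126 and 0.0126), and all 3 calls were lost with an estimated correlation (adjusted p = 0.412, 0.702 and 0.412). Their position relative to other genes turned to lower for all 3 lists after quantile normalization and for neuropeptides with medians subtracted. Called members were higher there too (21, 18 and 4 higher and 0 lower after quantile normalization, and 33 and 0 for neuropeptides with medians subtracted). Higher calls outnumbered lower ones in 35 of all 36 lists under each scaling alternative. Of 55 monoamine, acetylcholine and histamine genes, 17 were higher and 0 lower (17 and 0 adjusted over the list alone), 16 of them on compressed probe sets such as those of Drd5, Htr3a and Adrb1, and the uncompressed one was Maoa, the amine-degrading oxidase (0.23 ± 0.041, adjusted p = 0.00729). Of 56 neuropeptide and receptor genes, 8 were higher and 1 lower (1 and 0 adjusted over the list alone), among them Tac1 and the melanocortin receptor Mc4r (0.14). Of 13 pineal markers, 7 were higher and 0 lower (8 and 0 alone), all compressed, including Isl2 and Lhx4. The 1 uncompressed member was at -0.0975 (not called) and the mean difference over the list was -0.0073. Without chow 1 the neuropeptide list had adjusted p = 0.0722. With 1 array left out in turn, 2 (without powder 2) to 9 neuropeptide genes and 4 (without chow 2 or powder 1) to 7 pineal markers were higher.

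**Figure D2:**
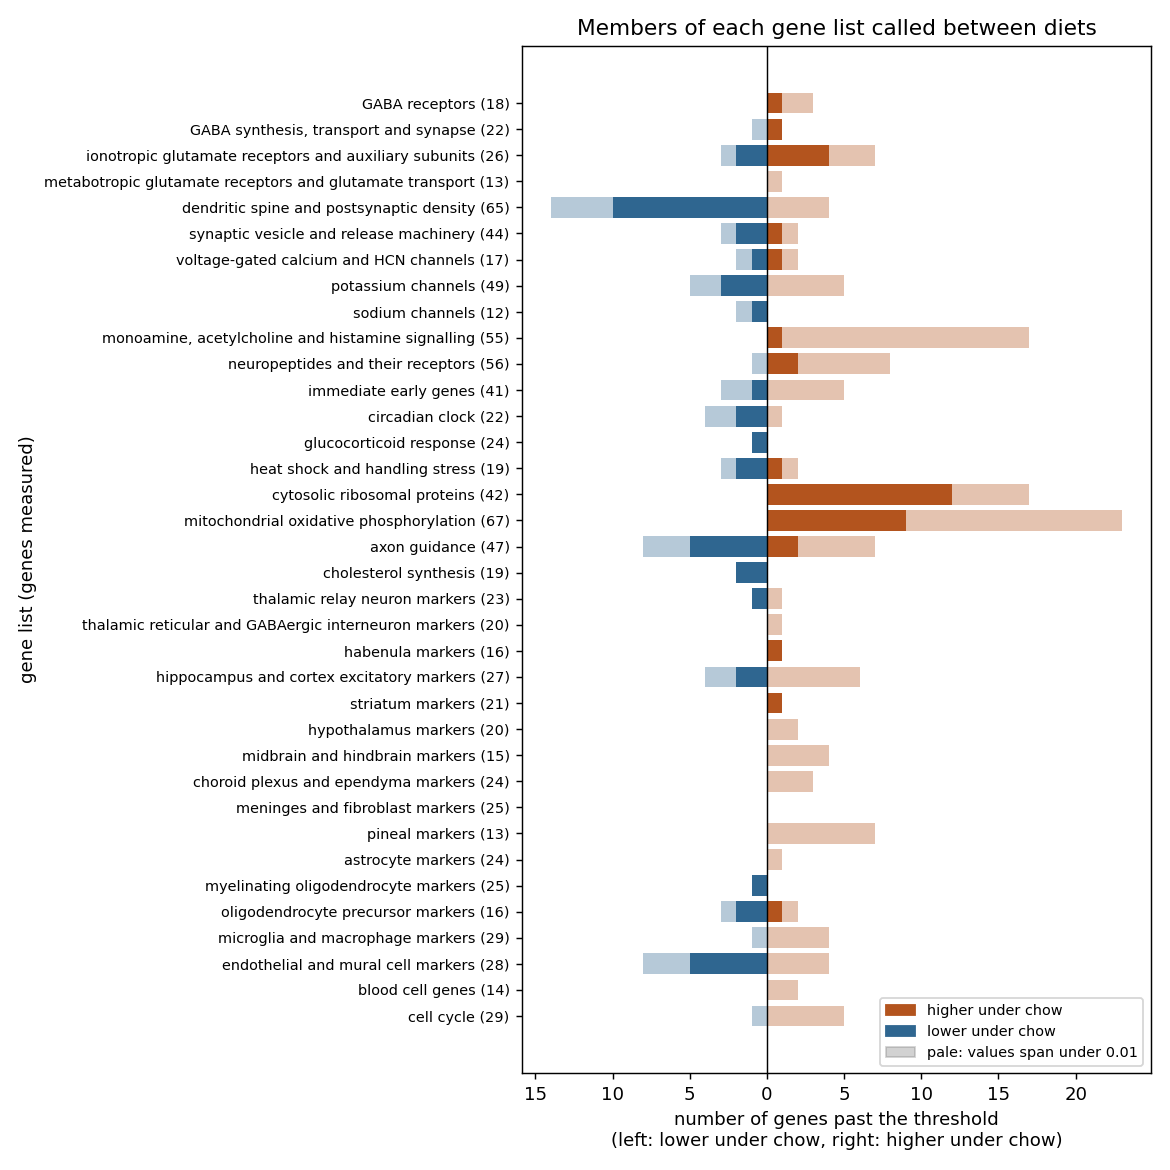
Number of members of each of 36 gene lists called higher (right) or lower (left) under chow, with measured members in parentheses; pale bars are genes whose 9 values span under 0.01 log2 units, whose directions a rescaling of the arrays can set. Ribosomal protein (17 to 0) and oxidative phosphorylation genes (23 to 0) lean higher, while their position relative to other genes turns lower after quantile normalization, and spine genes lean lower (4 to 14), a split that becomes 37 to 11 after quantile normalization.

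Among genes that respond to state or activity, clock and stress genes had single large calls and no list passed camera. Of 22 clock genes, 1 was higher and 4 lower (1 and 4 adjusted over the list alone; camera adjusted p = 0.137), with the repressors Cry2 at -0.39 ± 0.061 (adjusted p = 0.00568) and Cry1 at -0.17 ± 0.038 (adjusted p = 0.0144). Nr3c1, the glucocorticoid receptor, fell by 0.43 on the log2 scale (-0.43 ± 0.116, adjusted p = 0.0298) and was the 1 gene lower and 0 higher among 24 glucocorticoid response genes (0 and 0 alone; 0.846). Among 19 heat shock genes, 2 were higher and 3 lower (2 and 2 alone; 0.965), with the chaperone Hsp90ab1 at 0.22 and the transcription factors Hsf2 at -0.24 and Hsf1 at -0.17, the last not called without chow 4 (adjusted p = 0.0522). Of 41 immediate early genes, 5 were higher and 3 lower (0 and 0 alone; 0.584), of which only Klf4 was uncompressed (-0.31). Of 47 axon guidance genes, 7 were higher and 8 lower (9 and 8 alone; 0.801), including Unc5b (0.44), Epha5 (0.19), Epha3 (-0.24) and Nrp1 (-0.20). Of 19 cholesterol synthesis genes, 0 were higher and 2 lower (0 and 1 alone; 0.371), Hsd17b7 (-0.16) and Sc5d (-0.16). The count for glucocorticoid response genes was 0 without any 1 of 5 arrays (chow 4 and powder 1 to 4). With 1 array left out in turn, 2 to 4 immediate early genes were higher and 0 to 2 lower, 4 (without chow 2 or powder 3) to 7 axon guidance genes were higher, and 1 (without chow 4) to 3 heat shock and 1 to 3 cholesterol genes were lower. After quantile normalization and with medians subtracted, higher and lower calls were 11 and 3 and 13 and 4 for clock, 5 and 2 and 9 and 2 for glucocorticoid and 12 and 2 and 14 and 2 for heat shock genes. They were 19 and 1 and 29 and 1 for immediate early, 28 and 5 and 35 and 6 for axon guidance and 14 and 2 and 14 and 3 for cholesterol genes.

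Markers of vascular cells included some of the larger decreases. Of 28 endothelial and mural genes, 8 were lower and 4 higher under chow (11 and 6 adjusted over the list alone; camera adjusted p = 0.287), a split of 6 lower and 17 higher after quantile normalization and 7 and 20 with medians subtracted. Without chow 1, 4 were lower and 1 higher, and with any 1 array left out 4 to 8 were lower and 1 to 4 higher. Of the 9 uncompressed members, 5 were called, all lower, against 971 lower and 218 higher of all 2414 such genes. They were the drug efflux pump Abcb1a (-0.44 ± 0.080, adjusted p = 0.00829), the VEGF receptor Flt1 (-0.42), the pericyte gene Abcc9 (-0.28), Podxl (-0.17) and Slco1a4 (-0.15). Oligodendrocyte precursor genes gave 2 higher and 3 lower of 16 (2 and 3 alone; 0.761), with Tnr at 0.29 and Vcan at -0.22, and Vcan was 0.00013 and not called by the median over its probe sets. Myelinating oligodendrocyte genes gave 0 higher and 1 lower of 25, Mobp at -0.13 (0 and 0 alone; 0.801). Astrocyte genes gave 1 higher and 0 lower of 24 (0 and 0 alone; 0.801), and microglial genes 4 higher and 1 lower of 29 (3 and 0 alone; 0.137). Blood cell genes gave 2 higher and 0 lower of 14 (2 and 0 alone; 0.319), and cell cycle genes 5 higher and 1 lower of 29 (3 and 0 alone; 0.224), in each case on compressed probe sets. The astrocyte and microglial calls were also all on compressed probe sets. Without chow 1, 2 cell cycle genes were higher and 0 lower. Oligodendrocyte precursor calls fell to 1 lower without chow 2, chow 3, powder 1 or powder 3. Myelinating calls fell to 0 lower without chow 1, chow 2, chow 3, powder 1, powder 3 or powder 5. After quantile normalization and with medians subtracted, higher and lower calls were 11 and 1 and 10 and 1 for precursor, 7 and 2 and 14 and 1 for myelinating and 10 and 2 and 15 and 1 for astrocyte genes. They were 16 and 0 and 24 and 0 for microglial, 4 and 0 and 12 and 0 for blood cell and 15 and 0 and 29 and 0 for cell cycle genes.

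Thalamic relay neuron markers gave 1 higher and 1 lower of 23 (0 and 0 adjusted over the list alone; camera adjusted p = 0.137), the lower one being Amotl1 (-0.35). That list passed camera toward lower after quantile normalization (0 higher and 6 lower, adjusted p = 7.23e-11) and with medians subtracted (1 and 7, adjusted p = 1.63e-14), both at the assumed correlation of 0.01. Its estimated correlation was 0.466, at which adjusted p = 0.943 on the values as deposited. The reticular and GABAergic interneuron markers gave 1 higher and 0 lower of 20 (0 and 0 alone; 0.319). For neighbouring regions, striatum markers gave 1 higher and 0 lower of 21 (0 and 0 alone; 0.33) and habenula markers 1 and 0 of 16 (0 and 0 alone; 0.944), in both cases Tac1, with striatum markers at 11 and 0 under both scaling alternatives. Hippocampus and cortex markers gave 6 higher and 4 lower of 27 (8 and 4 alone; 0.166), with Prox1 at -0.35. Without chow 1 they gave 3 higher and 4 lower, and without chow 2 they gave 2 higher. With 1 array left out in turn, relay marker calls reached 3 higher (without chow 1) and 3 lower (without chow 3). The lower count fell to 0 without chow 4, powder 1, powder 2, powder 4 or powder 5. Hypothalamus markers gave 2 higher and 0 lower of 20 (0 and 0 alone; 0.134; 0 higher without chow 2 and 4 without chow 3), midbrain and hindbrain markers 4 and 0 of 15 (4 and 0 alone; 0.194), choroid plexus and ependyma markers 3 and 0 of 24 (1 and 0 alone; 0.287; 1 and 0 without chow 1, chow 2, chow 4 or powder 3) and meninges markers 0 and 0 of 25 (0 and 0 alone; 0.761). All higher calls of the hippocampus and cortex, hypothalamus, midbrain and hindbrain, and choroid plexus lists were on compressed probe sets. The uncompressed members of these lists had median differences of 0.0935, 0.171, -0.0452 and -0.0319. The single higher calls of the relay neuron and reticular lists were compressed too. Under each scaling alternative higher calls outnumbered lower ones in 35 of the 36 lists. Meninges markers passed camera toward lower under both, at the assumed correlation of 0.01. Their estimated correlation was 0.821, at which camera adjusted p = 0.966 on the values as deposited. On the chow 1 array the striatum score was 0.37, against -0.080 to 0.011 on the other 8 arrays, and the relay neuron score was -0.37, against -0.099 to 0.13. On that array Penk, the enkephalin precursor of striatal neurons, was at 10.7 against 8.60 to 9.32 on the others. Without chow 1 the difference in score between the diets went from 0.12 to 0.025 for striatum markers and from -0.18 to -0.086 for relay markers.

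**Figure D3:**
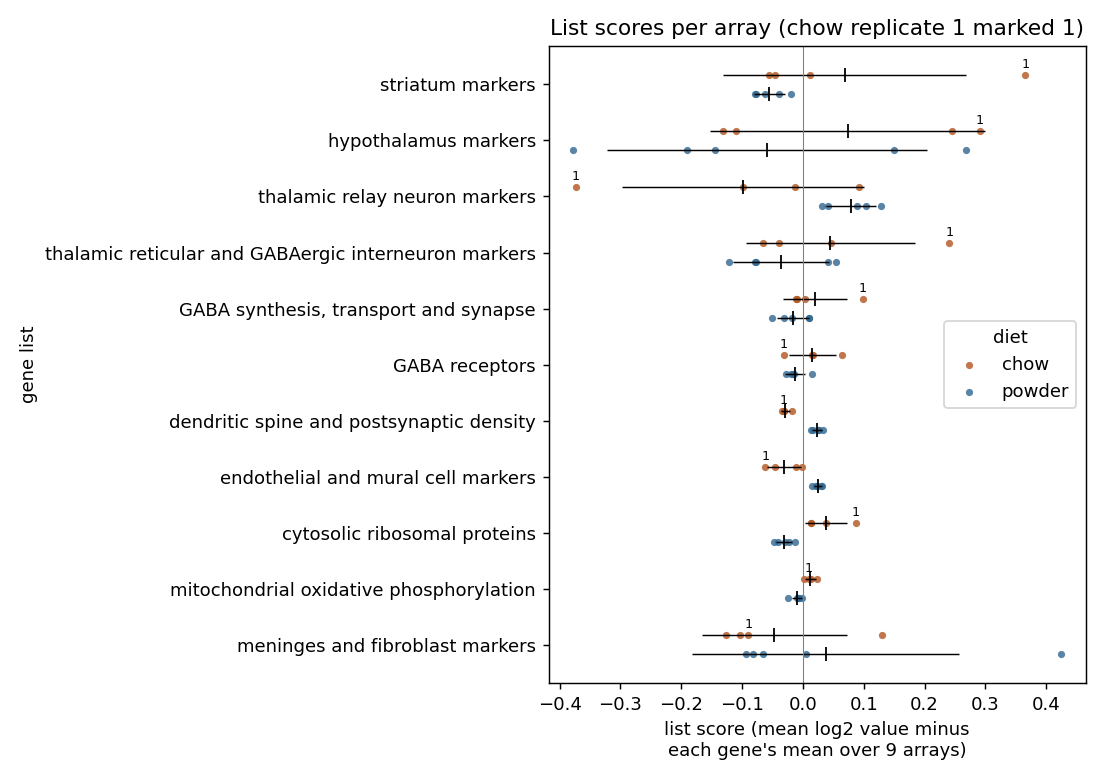
Scores of 11 gene lists on each array (mean log2 value of the members after each gene's mean over 9 arrays is subtracted), with bars for group means ± SD and chow replicate 1 marked 1. Chow 1 lies at 0.37 for striatum and -0.37 for relay neuron markers, while the spine list separates the 4 chow from the 5 powder arrays (difference -0.052 on the values as deposited).

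Of the 36 list scores, 6 passed an adjusted p of 0.05: besides the spine (-0.052), ribosomal protein (0.069) and oxidative phosphorylation (0.022) scores, these were the scores of potassium channels (-0.056), axon guidance (-0.014) and endothelial and mural cells (-0.055), each with exact permutation p = 0.00794, the smallest possible, and adjusted p = 0.0476. After quantile normalization 0 scores passed and the axon guidance score turned to 0.0011 (not called). With any 1 array left out 0 scores passed, in designs whose smallest possible exact p is larger.

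The arrays also differed as wholes. The first principal component held 52.8% of the variance and separated the diets (-8.42 ± 5.97 for chow and 6.74 ± 2.59 for powder, SD, n = 4 and 5, exact permutation p = 0.00794, adjusted p = 0.0159 over 4 measures). Chow 1 stood apart at -17.4. The 5' minus 3' value of the beta-actin control, a measure of how far labelled cRNA reaches toward the 5' end, was -1.52 ± 0.061 under chow and -1.65 ± 0.060 under powder (exact permutation p = 0.0238, adjusted p = 0.0317), and the same value of the Gapdh control differed by 0.094 (exact permutation p = 0.143). With the beta-actin value as a covariate, 724 genes were called, 213 higher and 511 lower. Of the 54 uncompressed genes called under the naming rule, 22 kept their call and direction with that covariate, among them Ralgps2, Kif1a, Tbl1x, Bicral, Dlg3 and Wasf1. Over the 1189 called genes spanning at least 0.01, the size of the difference with the covariate was a median 1.02 times that without it and its SE 1.61 times.

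**Figure D4:**
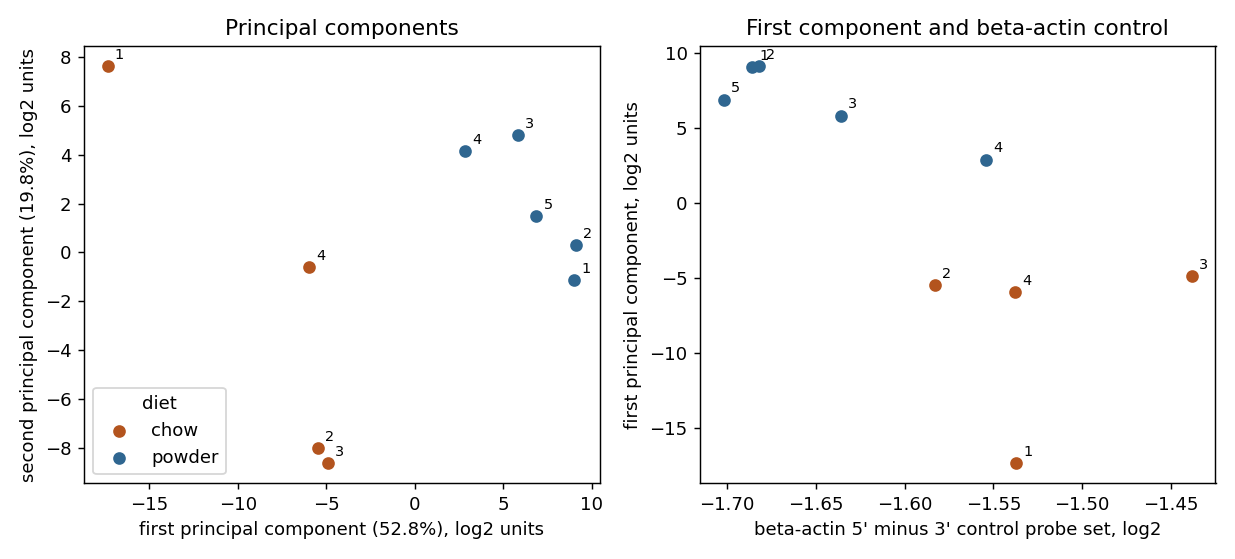
Left, the 9 arrays on the first (52.8%) and second (19.8%) principal components in log2 units; right, the first component against the beta-actin 5' minus 3' control value in log2 units. The chow arrays lie at negative and the powder arrays at positive values of the first component, with chow 1 farthest out at -17.4, and the control averaged -1.52 under chow and -1.65 under powder.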

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

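The tests of transcript coverage, hybridisation, scaling, summarisation, the share of GABAergic neurons and the exact tests against matched genes were chosen only after the results they bear on had been seen, as was the beta-actin covariate. Values were picked out here where 1 array lay far from the others of its group relative to the group's range. This held for 26 of 296 groups of values (8.78%), where chance gives about 1 in 20, and 10 of the 26 were on the chow 1 array.

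The chow 1 array stood apart in GABA genes, region markers, ribosomal protein genes and the array as a whole. Its score for GABA synthesis, transport and synapse was 0.098 (other chow arrays -0.011 to 0.0034), its striatum score 0.37 (others of its group up to 0.011) and its first principal component -17.35 (other chow arrays -5.96 to -4.90), with Gad2 at 9.10, Tac1 at 8.68, Gabrg1 at 8.22, Gabarap at 11.1 and Hsp90ab1 at 12.1, each the highest of the 4 chow arrays. Tissue of a neighbouring region in the dissected block is a candidate explanation, since the striatum score lay above the other 8 arrays by 3.92 times their range and 10 of 11 uncompressed striatum genes were above all other arrays, among them the abundant Penk (10.7 against 8.60 to 9.32), Ppp1r1b (9.18 against 7.74 to 8.01) and Drd2 (8.15 against 7.08 to 7.39), though 7 of the 21 measured striatum genes were also in another list. A larger share of reticular or other GABAergic neurons may also contribute, as the score of that list lay above the others by 1.05 times their range with 10 of its 14 uncompressed genes, Gad1 and Sst among them, above all other arrays and 4, Pvalb, Vip and Spp1 among them, below, but 11 of its 20 genes were in another list. How thalamus from different rats varies was not tested, and without chow 1 Gad2 was called (0.39, adjusted p = 0.0413). Of 23 uncompressed ribosomal protein genes, 21 were above and 0 below all other arrays on chow 1. Their list score was 0.087 there and at most 0.039 on the others. Without chow 1 the difference between the diets in that score went from 0.069 to 0.053.

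The number of genes that differed between the diets, 4684 of 14217, was not a matter of chance assignment, since 1 of 100 splits of the 9 arrays, the diet split itself, gave as many and the highest other split gave 1. For genes spanning at least 0.01, the values argue only against differences in the array medians, or in the distribution over all deposited probe sets, as the source. At least 94.4% of their 1189 calls kept call and direction under each scaling alternative. The alternatives moved these genes by a median of 0.0221 and 0.00657, against a median span of 0.372. Most probe sets are compressed, so both alternatives rest largely on near-constant values. A scaling difference before summarisation, or one confined to the uncompressed probe sets, could therefore not be tested. The authors' summarisation stays open. Of the 2382 genes that ranged over 0.01 or more within a diet group, 48.8% were called. That share cannot decide, since the method is unknown and escape from compression may itself depend on a difference between the diets. Scaling for compressed genes, different hybridisation of the arrays and different 5' to 3' coverage of transcripts cannot be told apart from the diets: 26.7% of the 3495 calls on compressed genes were kept after quantile normalization and 51.4% with medians subtracted, but both alternatives move these genes by more than they span, 0% of 4 hybridisation control transcripts had an exact p under 0.05 (95% limit 60.2%) against 46.1% of rat probe sets, with 14 of 16 control probe sets higher under chow, and 50.3% of 1574 pairs of called probe sets of 1 gene went opposite ways against 49.7% for independent directions, but 38% (95% interval 30.5 to 45.1) of 221 uncompressed pairs did against 45.9%, and with the beta-actin covariate the sizes of the 1189 uncompressed genes kept a median ratio of 1.02 while their SE grew 1.61 times. A different share of nuclear or unspliced RNA may contribute, since a gene lower under chow had a longer genomic span than a gene higher under chow with probability 0.697 (0.623 for uncompressed genes), with median spans of 37.7 and 14.5 kb. Higher background on the chow arrays stays open for the higher calls among dim probe sets (889 higher and 147 lower of the 5174 dimmest). Of 10 called olfactory receptor genes, 9, or 90% (exact 95% interval 55.5 to 99.7), were higher under chow, all compressed. That share cannot decide, since calls among the dimmest probe sets already lean the same way whatever the cause. The diet itself remains open beside these explanations.

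Ribosomal protein and oxidative phosphorylation genes were higher under chow on the values as deposited, but neither list passed camera with an estimated correlation (adjusted p = 0.652 for each). After quantile normalization more members were higher than lower (21 and 0, and 39 and 1), but so were all 14217 genes (8329 higher and 1000 lower). Those counts are therefore no sign of a shift of the lists. Relative to other genes the position of both lists turned to lower there (camera adjusted p = 0.295 and 0.397). A bias favouring genes of short genomic span is argued against as the whole source. Of 10000 random lists matched on genomic span and level, 0% had as high a mean t (3.02 for ribosomal proteins against a random median of 1.69, and 2.5 against 0.7 for oxidative phosphorylation). The lists were also higher under chow than their matched genes by 1.05 and 1.32 SD in a permutation of the arrays, which keeps the correlation between genes (exact p = 0.0238 and 0.00794, with 0.648 SD for ribosomal proteins without chow 1). Transcript length was not matched, so a bias by transcript length was not tested. A shift in level common to abundant genes is argued against as the whole source in the same way, with 0% of lists matched on level alone as high (random medians 0.0031 and -0.39, and 2.13 and 2.03 SD, exact p = 0.00794 for each). The random lists could draw members of both lists themselves. Their median of 1.69 therefore does not show how far other short genes of like level shared the ribosomal protein shift. The diet, cell composition, transcript length and the dependence on scaling stay open.

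The 5' minus 3' value of the beta-actin control, outside the main measurement, was 0.13 higher under chow (exact permutation p = 0.0238). On the uncompressed probe sets 2 further values lay apart, Bicral at 8.27 on powder 2 and Tnr at 8.82 on chow 2. Scores lay apart on powder 1 for meninges and fibroblasts (0.42), midbrain and hindbrain (0.17), monoamine, acetylcholine and histamine signalling (0.057) and pineal markers (0.017), on chow 2 for midbrain and hindbrain (0.18) and meninges and fibroblasts (0.13), and on powder 5 for ionotropic glutamate receptors (0.010). For 9 compressed values the distances were under 0.001 log2 units: on chow 1 Drd5 (7.0884) and Htr3a (6.8237), on powder 1 Lhx4 (6.6451), on powder 2 Tie1 (7.6589), on powder 3 Wasf3 (7.424), Isl2 (6.6954), Grik3 (7.1289) and Emx1 (7.1111), and on powder 5 Sema6d (10.854).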

How the results depend on the processing

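The alternatives that left out compressed probe sets, used the beta-actin covariate or asked for a minimum difference were chosen after seeing the data; the others were planned. The trended variance and array weights kept the 11 counts of probe sets, genes and lists within 1.5 times, the equal-variance test the 5 counts of probe sets it was run on, and an adjusted p under 0.1 its 6 counts; array weights moved the member counts of 3 lists for higher and 4 for lower calls. Of the 54 uncompressed genes called under the naming rule, 52 kept call and direction after quantile normalization, 53 with medians subtracted, 46 by the median over probe sets, 22 with the beta-actin covariate, 1 with the replicate number as a block and 48 to 52 with 1 array left out. Where no cause is given for a change below, the cause was not tested. The values are log2 on deposit, so the planned pseudocounts were not run, and signal over background could not be set. For gene lists the camera adjusted p is given, and a direction is that of a list relative to all other genes, which can be lower where its called members are higher.

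Quantile normalization called 17464 probe sets (15610 higher, 1854 lower) and 9329 genes (8329 and 1000), with 348 genes spanning at least 0.01 higher and 0 list scores. It moved 94% of the called compressed genes by more than they span, as subtracting medians did for 99.8%. The lists of monoamine signalling (0.318), neuropeptides (0.0802), ribosomal proteins (0.295), oxidative phosphorylation (0.397), pineal (0.521), habenula (0.0363) and astrocyte markers (0.0363) turned to lower, and the glucocorticoid (0.0128), relay neuron (7.23e-11), meninges (0.00209) and myelinating lists (0.0263) passed toward lower. Genes that turned to higher were Nlgn2 (0.014), Srgap2 (0.0081), Npy5r (0.0032), Erc1 (0.020), Dpp6 (0.023), Nalcn (0.026), Csnk1d (0.031), Clock (0.019), Sema6d (0.023), Chn1 (0.026), Lhfpl3 (0.019), Tek (0.018) and Tie1 (0.0073), and the axon guidance score turned to 0.0011.

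Subtracting array medians called 29347 probe sets (27206 higher, 2141 lower) and 13245 genes (12112 and 1133). The spine (0.000344), potassium channel (0.0235, turned), glucocorticoid (0.00129), relay neuron (1.63e-14) and meninges (0.000336) lists passed toward lower. The lists of monoamine signalling (0.949), ribosomal proteins (0.316), oxidative phosphorylation (0.0984) and pineal markers (0.495) no longer passed, and neuropeptides turned (0.28). Genes that turned to higher were Nlgn2 (0.0063), Npy5r (0.0062), Erc1 (0.0063), Dpp6 (0.0062), Nalcn (0.0030), Csnk1d (0.0062), Clock (0.0064), Sema6d (0.0063), Chn1 (0.0059), Tek (0.0061) and Tie1 (0.0062).

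Without the dimmest probe sets, 3367 probe sets and 1229 genes were higher, fewer having been tested; pineal markers lost their call (0.119) and microglial markers passed toward higher (0.0096). The median over probe sets gave 3 list shifts and 0 list scores, with neuropeptides (0.056) and pineal markers (0.107) lost. It turned Tbl1x (0.00025), Dlg3 (0.0046), Dpp6 (0.092), Csnk1d (0.00023) and Vcan (0.00013) to higher, Dlg4 (-0.088) and Kcne2 (-0.00048) to lower, and the axon guidance score to 0.0070. The rank product called 3169 probe sets, 1192 higher and 1977 lower. With an estimated correlation 0 lists shifted: monoamine signalling 0.412, neuropeptides 0.702, ribosomal proteins 0.652, oxidative phosphorylation 0.652, pineal 0.412. Under fry 8 lists passed, with GABA receptors (0.00364) and hippocampus and cortex (0.0395) gained toward higher, spine (0.00232) and clock (0.0273) gained toward lower, and neuropeptides lost (0.0889); fry does not compare a list with other genes.

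With compressed probe sets left out, 2884 probe sets (865 higher, 2019 lower) and 1677 genes (528 and 1149) were called, fewer having been tested, and 3 lists shifted. Monoamine signalling (0.361) and neuropeptides (0.0729) were lost, striatum markers (0.0275) passed toward higher, and Dlg4 (-0.18) and Dpp6 (0.19) turned with their representative probe set. With the beta-actin covariate, 1429 probe sets were called (567 higher, 862 lower; 100 and 421 of those spanning at least 0.01) and 724 genes (213 and 511; 33 and 252). Neuropeptides were lost (0.0799), choroid plexus (0.0435) and microglial markers (0.0406) passed toward higher, and myelinating markers turned (0.0447). A minimum difference of 0.1 left 2395 probe sets (705 higher, 1690 lower) and 1054 genes (189 and 865).

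With the replicate number as a block, 19 probe sets were called (1 higher, 18 lower; 1 and 17 of those spanning at least 0.01) and 11 genes (0 higher, 11 lower; 0 and 11), and 3 lists shifted, with neuropeptides (0.0708) and pineal markers (0.0885) lost. The values gave no sign that the numbers pair the samples, though so few arrays cannot exclude it. Deviations of same-numbered arrays correlated at -0.32, 0.16, -0.38 and -0.01, and chow 1 to 4 correlated best with powder 3, 1, 2 and 5. The block takes up most of the residual degrees of freedom.

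With 1 array left out in turn, fewer samples being tested, the probe sets higher under chow ranged from 3661 (without powder 1) to 4879, list shifts from 4 (without chow 1) to 8 (without chow 3), and list scores past the threshold fell from 6 to 0, in designs whose smallest possible exact p is larger. Neuropeptides ranged from 0.00537 to 0.0722 (without chow 1), relay neuron markers from 0.0252 (without chow 3) to 0.331, hypothalamus markers from 0.0241 (without powder 4) to 0.331 and microglial markers from 0.0343 (without chow 3) to 0.331. Over all alternatives the adjusted p ranged from 3.82e-11 to 0.652 for ribosomal proteins and for oxidative phosphorylation, from 0.000409 to 0.949 for monoamine signalling, from 0.00537 to 0.702 for neuropeptides and from 0.00364 to 0.521 for pineal markers.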

Other observations

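The families of genes described here were chosen by symbol only after the table of all genes had been seen, so their p-values describe families already seen to move and are no independent test. Each of 15 families was set against all other genes with camera as for the lists, with adjustment over the 15. Splicing factors of the SR family, which bind exons and guide the choice of splice sites, had 6 genes lower under chow and 0 higher of 10 measured, 4 of them on uncompressed probe sets, Srsf11 at -0.31 ± 0.023 (adjusted p = 0.00143), Srsf10 at -0.22, Srsf6 at -0.13 and Srsf1 at -0.11. Camera gave adjusted p = 0.00753, with 0.0348 after quantile normalization and 0.038 with medians subtracted, lower in each, and adjusted p = 0.0702 with an estimated correlation. RNA-binding motif genes gave 2 higher and 15 lower of 35 (adjusted p = 0.0138, and 0.189 with an estimated correlation), lower relative to other genes in all 3 scalings but past the threshold only as deposited (0.694 and 0.113), with Rbm12b at -0.22, Rbm15 at -0.21 and Rbm5 at -0.21.

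For families of protein turnover and of lysine methylation, camera passed as deposited and was lost with an estimated correlation. Ubiquitin-specific proteases, which remove ubiquitin from proteins, gave 0 higher and 18 lower of 42, with Usp40 at -0.33 ± 0.043 and Usp48 at -0.26 ± 0.030 (camera adjusted p = 0.00088, 0.0566 with an estimated correlation, and 0.772 and 0.088 under the scaling alternatives, still lower). Proteasome subunits gave 9 higher and 4 lower of 37 (adjusted p = 0.0138, and 0.459 with an estimated correlation), higher relative to other genes in all 3 scalings (0.0348 after quantile normalization and 0.113 with medians subtracted), with Psmb2 at 0.25, Psma6 at 0.22 and Psmc1 at 0.20. Lysine methyltransferases and demethylases gave 2 higher and 16 lower of 23, with Kmt5c at -0.32, Kdm7a at -0.29 and Kmt2c at -0.26 (0.00088, and 0.0664 with an estimated correlation), and their position relative to other genes turned after quantile normalization (0.568). Zinc finger genes gave 20 higher and 72 lower of 219, with Zfp326 at -0.37 (0.00088, and 0.0566 with an estimated correlation), also turning after quantile normalization (0.727). Olfactory receptor genes gave 9 higher and 1 lower of 18, all compressed (0.00088, and 0.189 with an estimated correlation), turning after quantile normalization (0.552). The other 8 families did not pass on the values as deposited, and of these the mitochondrial ribosomal proteins passed toward higher after quantile normalization (3.72e-07, against 0.213).

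Hypothalamic peptide genes varied widely between arrays of both diets. Oxt, the oxytocin gene, was at 9.87 on chow 1 and between 7.09 and 10.4 on the other arrays, Avp, the vasopressin gene, at 9.67 and between 7.39 and 10.4, and Pmch, which encodes melanin-concentrating hormone, at 11.2 and between 8.56 and 11.2. The hypothalamus score ranged from -0.13 to 0.29 on the chow arrays and from -0.38 to 0.27 on the powder arrays, and the diets differed by less than that spread (0.13, exact permutation p = 0.429, adjusted p = 0.644). Without chow 1 the difference between the diets was 0.060.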
